A study of Mus musculus with 11 samples.

How the data were processed

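Gene expression was measured by RNA sequencing in 8 libraries of effector CD8 T cells, 4 from WT and 4 from Dot1L KO mice. Per the labels' protocols, cells were sorted by flow cytometry from spleens on day 7 of infection, only RNA with an integrity number above 8 was used, and strand-specific mRNA libraries were sequenced as single reads of 65 bases. Read counts per Ensembl gene were deposited by the authors as whole numbers, not normalised, with 1 column per library and none pooled. The submitters' processing notes name TopHat2 2.1.0 and HTSeq 0.9.1 and the builds GRCm38 and mm10. The annotation release, the strand setting and the filters on reads are not given in the sources used here. Reads that fit several near-identical genes may have been left out or split, which lowers or blurs the counts of families such as the Ly49 receptors. The 3 H3K79me2 ChIP samples were not analysed here.

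The count table held 52636 genes and no row without a gene. Symbols were matched by Ensembl identifier for 52403 of them. Coordinates were matched by symbol from a RefSeq table of GRCm38.p6 for 11792 of the 12310 tested genes (95.8%). Sex was read from Xist against 4 Y-linked genes. Total counts ranged from 16376310 to 24585034 per library. At this depth, Dot1l was covered by 2409 to 3615 reads per library. The labels do not say outright that each library came from a separate mouse, so p-values measure the spread between these libraries.

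KO was compared with WT using edgeR 4.0.16 in R 4.3.3: TMM factors, genes kept by filterByExpr (minimum count 10, minimum total 15), robust dispersions, and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. All 4 libraries of each group entered the fit with no covariate. Values are CPM, counts scaled to TMM-normalised library sizes, computed from the deposited counts. The SE of a log2 fold change was derived from the fold change and its F statistic. Gene lists were tested with camera in limma 3.58.1 on voom values, with 28 lists as 1 family; a further list held the sex genes. Camera asks whether a list's genes stand higher or lower than other genes, and its preset correlation of 0.01 makes smaller p-values than an estimated one where list members vary together between libraries. The single value of Dot1l was also tested by an exact permutation test. Each library pair differed by more than sampling noise in a chi-square comparison of counts.

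Dot1l was named first. From each list up to 4 members with the smallest p were eligible to be named, and part of them are named. The rule also took the 10 called genes with the largest increase and the 10 with the largest decrease, with a mean of at least 2 CPM and groups that do not overlap, and edgeR called none. Klrk1, Klra7, Klre1, Klrc1, Klrc2, Klrd1, Fos, Jun, Ahdc1, Hdac7, Tcf7, Ccr7, Mki67, Gzmb, Lyz2, Cd44, Cd8a, Cd8b1, Lef1, Epx, Prg2, Il1b and Cd14 were named after their values were seen. Some genes are not reported here.

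The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, no low count filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, sex as a covariate, each library left out in turn, camera with an estimated correlation, fry, and windows of 5 and 20 Mb around Dot1l. Lists, tests and these alternatives were fixed before the data were examined. Fits without WT replicate 4 and KO replicate 1, the libraries least correlated with the rest, were added after seeing the data, with edgeR, edgeR with sex, DESeq2 and an estimated correlation. Leaving out libraries chosen this way narrows the spread between the remaining ones, so those fits stand beside the fits of all 8 libraries and do not replace them. In all, 22 settings were run beside the first fit. The edgeR test was tested on simulated counts with 200 genes changed by known folds. Each gene was drawn on its own, so libraries that shift many genes together are not reproduced. With the spread of the 6 libraries it recovered 14.7%, 59.0% and 84.4% of genes changed 1.5-fold, 2-fold and 4-fold among 12310 genes. These were 11, 36 and 54 genes, beside 13 unchanged genes called.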

Results

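Messenger RNA was counted per gene in effector CD8 T cells, the cytotoxic lymphocytes that expand against an intracellular infection. The cells came from spleens of C57BL/6 mice infected intravenously with 10000 CFU of Listeria monocytogenes and were sorted by flow cytometry on day 7 as CD8 T cells by surface markers, among them presence of CD44. The design set 4 libraries from WT mice against 4 from Dot1L KO (knockout) mice, whose floxed Dot1l alleles were combined with a Cre transgene. Dot1l encodes the methyltransferase that places methyl groups on lysine 79 of histone H3, a mark of transcribed genes. By their labels, 3 of the 4 WT libraries came from mice that also carried Cre, and WT replicate 1 did not. Total counts were 19857749, 22691867, 23818957 and 16376310 for WT replicates 1 to 4, and 17064564, 24585034, 20590723 and 18577063 for KO replicates 1 to 4. Of 52636 genes in the count table, 12310 had enough counts to be tested. Each group held 2 male and 2 female libraries by their Xist and Y-linked transcripts. The series also lists 3 WT H3K79me2 ChIP samples, which were not analysed here.

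The libraries of each group differed in their marker transcripts. WT replicate 4 had low transcripts of proliferation and cytotoxicity and high transcripts of resting T cells. Its Mki67, a marker of dividing cells, was 31.6 CPM (counts scaled to library size) against 1427 to 2247 CPM in the 6 libraries other than itself and KO replicate 1, and its Gzmb, which encodes the cytotoxic protease granzyme B, was 9.64 CPM against 915.7 to 2453 CPM. Its Tcf7, which encodes a transcription factor of resting and memory T cells, was 2079 CPM against 52.4 to 304.1 CPM, and its Cd44 was 22.0 CPM against 251.0 to 329.1 CPM. Its Cd8a, at 1697 CPM, lay within the range of 1617 to 2002 CPM of those 6 libraries. KO replicate 1 had Lyz2, a lysozyme gene of macrophages and neutrophils, at 718.7 CPM against 18.2 to 54.3 CPM, and Tcf7 at 717.3 CPM. The highest correlation of log2 CPM with any other library was 0.886 for WT replicate 4 and 0.944 for KO replicate 1, and at least 0.973 for each of the other 6 libraries.

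**Figure D1:**
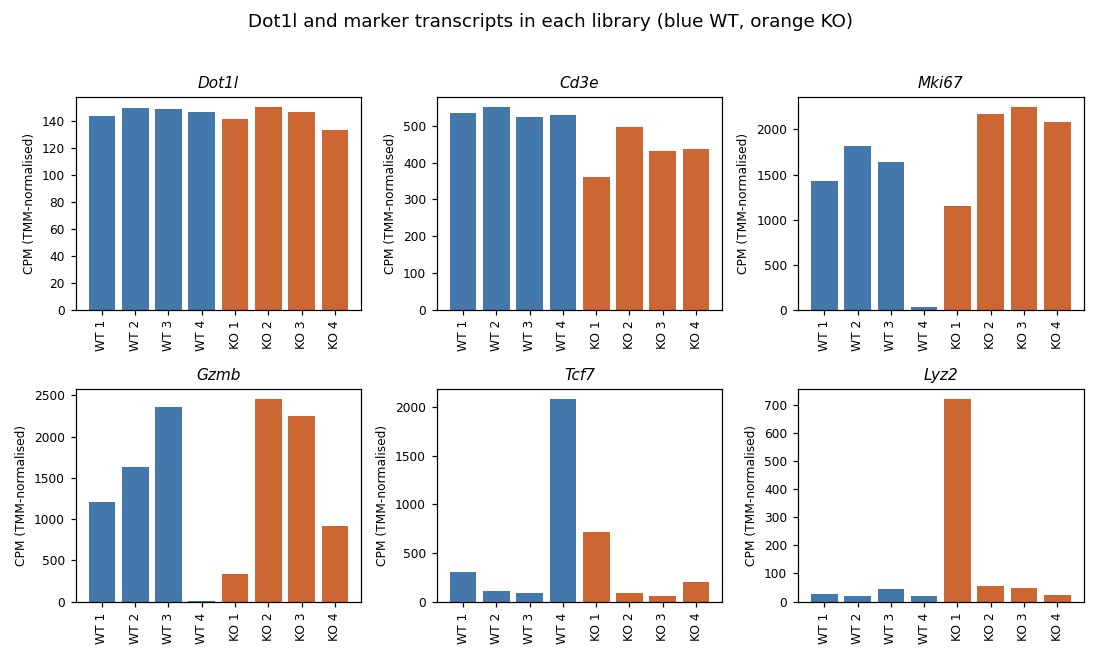
Normalised CPM of Dot1l and of 5 marker transcripts in each of the 8 libraries, 1 bar per library, WT in blue and KO in orange, on linear axes from 0. Dot1l lies between 132.7 and 149.8 CPM throughout, while WT replicate 4 stands apart in Mki67, Gzmb and Tcf7 and KO replicate 1 in Lyz2.

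The first comparison asked whether the targeted gene differed between the groups. Dot1l transcripts differed between KO and WT cells by less than the spread between libraries. Dot1l (ENSMUSG00000061589; GRCm38 chromosome 10, 80755101 to 80795461) was at 146.8 ± 2.92 CPM in WT and 142.5 ± 7.54 CPM in KO (mean ± SD, n = 4 each). Every library lay between 132.7 and 149.8 CPM. The log2 fold change was -0.04 (SE 0.07), a fold of 0.970 with a 95% interval from 0.856 to 1.10, and the adjusted p from edgeR's quasi-likelihood test was 0.846. A two-sided exact permutation test gave p = 0.371, where the smallest p the design allows is 0.0286. Which exon the floxed allele loses is not given in the sources used here, and counts summed over the gene do not check the KO labels.

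The second comparison asked which genes depend on Dot1L in effector CD8 T cells. No gene passed an adjusted p of 0.05 with all 8 libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; the smallest adjusted p was 0.704. At an unadjusted p under 0.05 there were 790 genes, 361 with higher and 429 with lower values in KO, and 412 without WT replicate 1. DESeq2 called 13 genes on the same libraries, 4 higher and 9 lower in KO, 6 of them at least 2-fold. In 618 genes (5.02% of those tested) all 4 KO libraries lay on one side of all 4 WT libraries, with KO higher in 205 and lower in 413. The mean share over the 35 splits of the libraries into 4 and 4 is 2.86%. Genes vary together between libraries, so a single split can lie well above that mean, and 5.02% does not show an excess beyond chance. The other splits gave 84 to 2599 genes at an unadjusted p under 0.05 in edgeR, a range that holds the real 790. On counts simulated for this comparison with the spread of the 8 libraries, over 12310 genes, the test recovered 0% of genes changed 1.5-fold, 19.2% of those changed 2-fold and 61.2% of those changed 4-fold. Each gene was simulated on its own, without libraries that shift many genes together, so these shares need not hold for the real counts. With no gene called by edgeR, the planned share of higher genes by expression level could not be formed.

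Among the genes called by DESeq2, Ahdc1, a nuclear protein gene, and Hdac7, a histone deacetylase gene expressed in T cells, were both lower in every KO library than in any WT library. Both were chosen after their values were seen. Ahdc1 was at 80.5 ± 1.43 CPM in WT and 62.7 ± 2.31 CPM in KO (SD, n = 4 each), with a DESeq2 adjusted p of 0.000386. Hdac7 was at 345.6 ± 43.9 CPM in WT and 201.8 ± 36.5 CPM in KO, with a DESeq2 adjusted p of 0.0310. In edgeR both had an adjusted p of 0.704. The 4 genes higher in KO included Epx and Prg2, which encode granule proteins of eosinophils, with DESeq2 log2 fold changes of 6.26 (SE 1.13) and 4.39 (SE 0.86) and adjusted p of 0.000386 and 0.00132. Both were chosen after their values were seen. Epx was at 0.487 to 10.01 CPM in KO and at most 0.121 CPM in WT, and Prg2 at 0.634 to 18.4 CPM and at most 0.600 CPM. In edgeR Prg2 had an adjusted p of 0.704, and Epx had too few counts to be tested. Without WT replicate 4 and KO replicate 1, Epx kept its DESeq2 call (adjusted p 0.000272) and Prg2 lost it.

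Gene lists fixed before the data were examined were tested with camera against all other genes, with a preset correlation between genes of 0.01. Of 28 lists, 12 passed an adjusted p of 0.05, 8 towards higher and 4 towards lower values in KO. None passed with an estimated correlation, where the smallest adjusted p was 0.700, or with fry, where it was 0.449. No single member of any list passed edgeR's test, over all genes or adjusted over the list alone.

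Genes of cell division had higher values in KO. All 28 G2 and mitosis genes had positive log2 fold changes, with a median of 0.61, and the list's camera adjusted p was 9.01e-06 (adjusted p = 0.762 with an estimated correlation). Ccnb1, which encodes cyclin B1, had a log2 fold change of 0.79 (SE 0.87), and Cks2, a partner of cyclin-dependent kinases, 0.57 (SE 0.61). Of 29 S phase genes, 28 had positive values, with a median of 0.54 and an adjusted p of 3.13e-06 (adjusted p = 0.762 with an estimated correlation). Rrm1, a ribonucleotide reductase subunit gene, had a log2 fold change of 0.70 (SE 0.53), and Mcm7, of the replicative helicase, 0.46 (SE 0.35). With WT replicate 4 left out, the log2 fold changes of Ccnb1, Cks2, Rrm1 and Mcm7 fell to 0.38, 0.19, 0.35 and 0.20. WT replicate 4 lay 5.40 log2 units below the median of the other 6 libraries in the median of the mitosis genes, and KO replicate 1 0.73 log2 units below. The mitosis list had a median of 0.39 without WT replicate 4 and KO replicate 1, with an adjusted p of 9.09e-12 (adjusted p = 0.569 with an estimated correlation). Its mean log2 CPM was 6.84, 7.28 and 7.41 in WT replicates 1 to 3 and 7.67, 7.62 and 7.41 in KO replicates 2 to 4. KO replicate 4 was thus level with WT replicate 3, and the lowest value was that of WT replicate 1, the library without Cre.

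Genes of glycolysis and the respiratory chain went the same way. Of 19 glycolysis genes 15 had higher values in KO, with a median of 0.32 and a camera adjusted p of 0.00255, and of 26 respiratory chain genes 25 did, with a median of 0.18 and an adjusted p of 0.000475. Both had an adjusted p of 0.762 with an estimated correlation. Tpi1 and Pgam1, 2 glycolytic enzyme genes, had log2 fold changes of 0.87 (SE 0.40) and 0.45 (SE 0.18), and Cox7a2 and Atp5b, of the respiratory chain and the ATP synthase, 0.41 (SE 0.22) and 0.21 (SE 0.15). The respiratory chain list had an adjusted p of 0.160 without WT replicate 4, where Cox7a2 and Atp5b fell to 0.24 and 0.13, and of 0.0550 with quality weights. Without both WT replicate 4 and KO replicate 1 it passed at 0.00376, with 24 of 26 higher and a median of 0.13 (adjusted p = 0.717 with an estimated correlation), and the glycolysis list at 0.0137 (adjusted p = 0.714 with an estimated correlation). Mean log2 CPM of the respiratory chain list was 6.53, 6.835 and 6.80 in WT replicates 1 to 3 and 6.90, 6.91 and 6.73 in KO replicates 2 to 4. For glycolysis it was 6.13, 6.45 and 6.54, and 6.69, 6.91 and 6.35. In both lists KO replicate 4 lay below WT replicates 2 and 3, and the lowest value was that of WT replicate 1, the library without Cre.

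Naive and memory genes had lower values in KO in 22 of 24 members, with a median log2 fold change of -0.79 and a camera adjusted p of 0.000335 (adjusted p = 0.762 with an estimated correlation). Klf2, a transcription factor of resting T cells, was at 291.3 ± 69.5 CPM in WT and 189.8 ± 31.4 CPM in KO (SD, n = 4 each), a log2 fold change of -0.62 (SE 0.19). The costimulatory receptor gene Cd27 had a log2 fold change of -0.61 (SE 0.22), and Dapl1 one of -5.78 (SE 1.95), where 158.9 CPM in WT replicate 4 faced 0.600 to 4.72 CPM in the other 3 WT libraries. This list was 2.24 log2 units higher in WT replicate 4 than in the other 6 libraries, in its median member, and without that library its adjusted p was 0.0738 and Dapl1 had a log2 fold change of -1.48. Without both WT replicate 4 and KO replicate 1, 22 of 24 members were lower, with a median of -0.35 and an adjusted p of 3.92e-05 (adjusted p = 0.250 with an estimated correlation). The list's mean log2 CPM was 6.10, 5.50 and 5.45 in WT replicates 1 to 3 and 5.41, 5.07 and 5.44 in KO replicates 2 to 4. KO replicate 4 was thus close to WT replicate 3, and the highest value was that of WT replicate 1, the library without Cre.

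Effector genes passed camera towards higher values in KO, with 15 of 24 members higher, a median of 0.09 and an adjusted p of 0.0210 (adjusted p = 0.936 with an estimated correlation). Fasl, a death ligand gene, had a log2 fold change of 0.60 (SE 0.78), Bhlhe40, a transcription factor gene, 0.67 (SE 0.83), and the chemokine gene Ccl5 -0.63 (SE 0.80). The cytokine gene Tnf had 0.51 (SE 0.41). With WT replicate 4 left out these 4 genes had 0.20, 0.27, -1.04 and 0.28; Ccl5 had -0.12 and Tnf 0.30 without WT replicate 1, and Bhlhe40 1.13 and Tnf 0.90 without WT replicate 2. The direction rested on WT replicate 4, whose effector genes lay 4.32 log2 units below the other 6 libraries: without it the list passed towards lower values in KO, with an adjusted p of 0.00218, and without both WT replicate 4 and KO replicate 1 it was lower at 0.121. Without KO replicate 4 the adjusted p was 0.0831, towards higher values. The 18 genes of inhibitory receptors did not pass (adjusted p 0.209), with Cd160 at 0.90 (SE 0.59) and Cd38 at 0.87 (SE 0.64) on the log2 scale, or 0.53 and 0.49 without WT replicate 4.

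Genes of the T cell receptor complex and its proximal signalling had lower values in KO in 19 of 22 members, with a median log2 fold change of -0.20 and a camera adjusted p of 5.97e-06 (adjusted p = 0.762 with an estimated correlation). Cd3e, a chain of the receptor complex, was at 534.7 ± 11.9 CPM in WT and 431.9 ± 55.5 CPM in KO (SD, n = 4 each), and all 4 KO libraries lay below all 4 WT libraries. Prkcq, a kinase gene of this pathway, had a log2 fold change of -0.36 (SE 0.12), Plcg1 one of -0.36 (SE 0.14), and Cd5, which encodes an attenuator of receptor signals, one of -0.74 (SE 0.30). In its median member the list lay 0.43 log2 units lower in KO replicate 1 than in the other 6 libraries; that library also had high myeloid markers, and Cd8a at 955.0 CPM against 1915 to 2002 CPM in the other 3 KO libraries. The list's adjusted p was 0.00836 without KO replicate 1. Without it and WT replicate 4, 18 of 22 members were lower, with a median of -0.13 and an adjusted p of 0.00117 (adjusted p = 0.250 with an estimated correlation).

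Immediate early genes, which respond within minutes to receptor signals and to tissue dissociation, had lower values in KO in 19 of 22 members. Their median log2 fold change was -0.42, and the camera adjusted p was 9.01e-06 (adjusted p = 0.700 with an estimated correlation). Ier2 was at 71.4 ± 10.9 CPM in WT and 49.6 ± 2.73 CPM in KO, Jund at 41.5 ± 2.84 and 31.03 ± 4.68 CPM, and Fosb at 7.94 ± 4.57 and 2.32 ± 0.682 CPM (SD, n = 4 each). Zfp36, which encodes an mRNA decay factor, had a log2 fold change of -0.78 (SE 0.29). KO replicate 1 stood apart, with a mean of 4.69 log2 CPM over the list against 3.87 to 4.01 in the other 3 KO libraries and 4.42 to 4.65 in WT. Without WT replicate 4 and KO replicate 1 the median was -0.54 and the adjusted p 3.45e-06 (adjusted p = 0.208 with an estimated correlation); 11 members passed edgeR's test adjusted over the list alone, and none over all genes.

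Genes of the NK receptors and innate-like T cells did not pass in the first fit of all 8 libraries: 15 of 24 had lower values in KO, the median log2 fold change was -0.30, and camera's direction was up at an adjusted p of 0.987, so that median and test differ in sign. Over the alternatives the adjusted p ranged from 1.32e-08 to 0.997. With all 8 libraries and quality weights the list passed towards lower values in KO at 7.21e-05, and without WT replicate 4 alone at 4.99e-06, while with upper-quartile factors it was down at 0.927. The quality weights were 0.091 for WT replicate 4 and 0.326 for KO replicate 1, against 0.631 to 3.66 for the other 6 libraries. The weighted fit thus comes near to leaving out WT replicate 4 and is not separate support from all 8 libraries. Without WT replicate 4 and KO replicate 1, an alternative chosen after seeing the data, it also passed towards lower values, with a median of -0.57 and a camera adjusted p of 8.40e-07 (adjusted p = 0.208 with an estimated correlation). In the same 6 libraries all 13 neutrophil markers had higher values in KO, in the list mean mainly against WT replicates 1 and 2. Their median was 2.35 and the camera adjusted p 1.81e-09 (adjusted p = 0.405 with an estimated correlation). Of the NK receptor list, 12 members passed edgeR's test adjusted over the list alone in those libraries, and none over all genes. Klrk1, which encodes the activating receptor NKG2D, was at 471.6 ± 38.2 CPM in WT and 237.1 ± 4.98 CPM in KO (SD, n = 3 each), a log2 fold change of -0.99 (SE 0.08) with an edgeR adjusted p of 0.0755 over all genes and a DESeq2 adjusted p of 1.39e-21. The Ly49 receptor gene Klra7 was at 22.4 ± 7.63 and 3.10 ± 0.767 CPM (log2 fold change -2.85, SE 0.32), Klre1 at 60.8 ± 21.1 and 19.6 ± 6.65 CPM, and Klrd1, which encodes CD94, at 222.5 ± 12.7 and 152.4 ± 24.4 CPM. With all 8 libraries the log2 fold changes of Klrk1, Klra7, Klre1 and Klrd1 were -0.77, -1.56, -1.31 and -0.41, with edgeR adjusted p from 0.704 to 0.722, and that of Klra7 was -2.46 without KO replicate 1. Klrc2 and Klrc1, which encode NKG2 receptors, had log2 fold changes of -0.77 (SE 0.15) and -0.38 (SE 0.07) in the 6 libraries, and -0.25 (SE 0.80) and -0.09 (SE 0.88) with all 8, where leaving out 1 library gave -0.66 to 0.057 and -0.50 to 0.12. Klra7 belongs to a family of near-identical genes, and its counts may hold reads of its relatives. These 6 receptor genes were chosen after their values were seen.

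**Figure D2:**
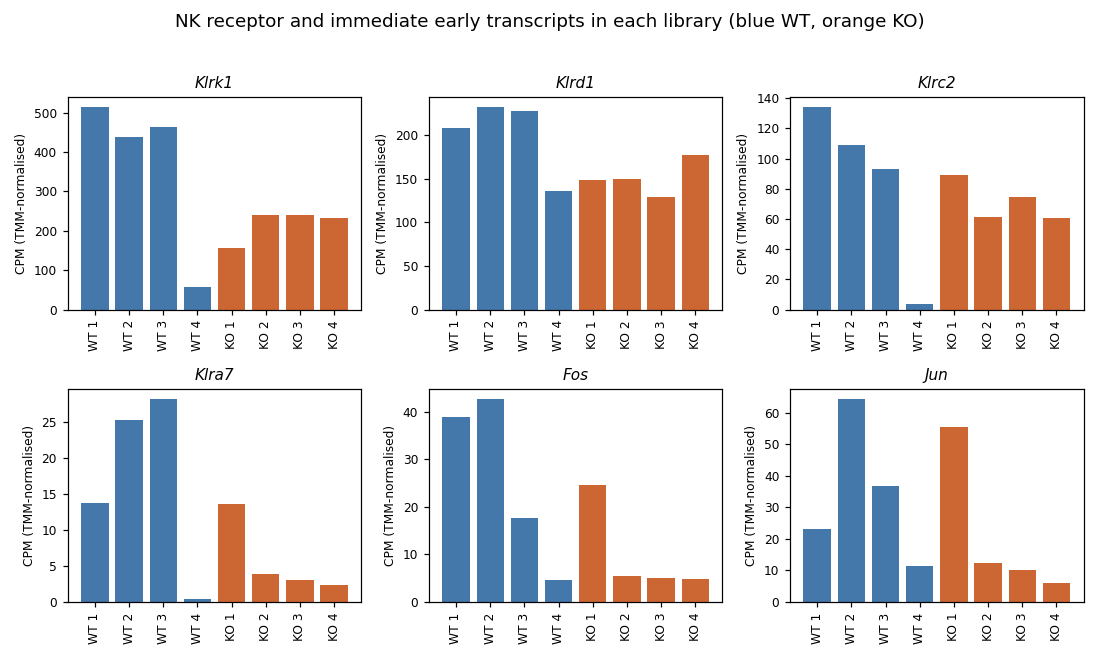
Normalised CPM of 4 NK receptor genes and of Fos and Jun in each of the 8 libraries, 1 bar per library, WT in blue and KO in orange, on linear axes from 0. Klrk1 lies between 231.3 and 240.3 CPM in KO replicates 2 to 4, below WT replicates 1 to 3 at 438.7 to 513.4 CPM, and WT replicate 4 is at 57.9 CPM.

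With WT replicate 4 and KO replicate 1 left out, edgeR still called 0 genes, with 1317 at an unadjusted p under 0.05. A split that mixes the groups, WT replicates 1 and 2 with KO replicate 4 against the other libraries, gave 1391 such genes. DESeq2 called 94 genes, of which 18 were higher and 76 lower in KO and 32 changed at least 2-fold. In both sets of libraries, 8 genes were called by DESeq2. Fos, a gene of the AP-1 transcription factor, was at 33.1 ± 13.5 CPM in WT and 5.03 ± 0.405 CPM in KO (SD, n = 3 each; DESeq2 adjusted p 2.83e-14), and Jun, its partner, at 41.4 ± 20.96 and 9.47 ± 3.20 CPM (DESeq2 adjusted p 1.73e-05). In edgeR their adjusted p was 0.320 and 0.453. Among the genes higher in KO were Il1b and Cd14, genes of myeloid cells, with a DESeq2 adjusted p of 0.0199 each, where edgeR gave 0.453 for both. These 4 genes were chosen after their values were seen. With all 8 libraries the log2 fold changes of Fos and Jun were -1.39 (SE 0.80) and -0.69 (SE 0.78); without KO replicate 1 they were -2.38 and -1.84, and Jun had -0.18 without WT replicate 2 and -0.39 without KO replicate 4.

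Partners of DOT1L and members of the super elongation complex had lower values in KO in 14 of 18 genes, with a median log2 fold change of -0.22 and a camera adjusted p of 0.00298 (adjusted p = 0.762 with an estimated correlation). Men1, which encodes menin, had a log2 fold change of -0.31 (SE 0.12). The adjusted p of this list was 0.116 without WT replicate 4 and 0.0990 with quality weights. Without both WT replicate 4 and KO replicate 1 it was 0.0336, with 15 of 18 lower and a median of -0.11 (adjusted p = 0.609 with an estimated correlation). The list's mean log2 CPM was 6.78, 6.60 and 6.53 in WT replicates 1 to 3 and 6.51, 6.45 and 6.61 in KO replicates 2 to 4. KO replicate 4 thus lay above WT replicates 2 and 3, and the highest value was that of WT replicate 1, the library without Cre. Members of the Polycomb complexes did not pass (23 genes, median -0.03, adjusted p 0.812), with Jarid2 at -0.31 (SE 0.13) and Rbbp7 at 0.36 (SE 0.18) on the log2 scale, and 0.23 for Rbbp7 without WT replicate 4. Of 36 genes commonly silenced by Polycomb in lymphocytes, most of them developmental transcription factor genes, only 6 were expressed enough to be tested, and they did not pass (adjusted p 0.192). Of these, Cdkn2a, which encodes cell cycle inhibitors, had a log2 fold change of 1.26 (SE 1.02), or 1.99 without WT replicate 2, and the transcription factor gene Gata2 one of 2.89 (SE 1.38), with Gata2 at 27.2 CPM in KO replicate 1 and 0.487 to 0.861 CPM in the other 3 KO libraries, and -0.53 on the log2 scale without KO replicate 1. This list passed without KO replicate 2, with an adjusted p of 0.0455, and had 0.746 without KO replicate 1 and, with all 8 libraries, 0.762 with an estimated correlation.

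Markers of 3 other kinds of cell had higher values in KO, and KO replicate 1 was high in many of them, as KO replicate 4 was in erythroid markers. All 13 neutrophil markers had higher values (median 1.85, adjusted p 3.49e-07), as did 15 of 20 monocyte, macrophage and dendritic cell markers (median 1.99, adjusted p 0.000335) and all 14 erythroid and platelet markers (median 1.79, adjusted p 0.0482). With an estimated correlation their adjusted p was 0.762, 0.762 and 0.895. Csf3r, a receptor gene of neutrophils, was at 83.6 CPM in KO replicate 1 and 4.68 to 11.3 CPM in the other 3 KO libraries, and the macrophage gene C1qc at 40.2 CPM and 5.06 to 6.00 CPM. Slc4a1, of red cells, was at 121.2, 9.74, 11.6 and 173.8 CPM in KO replicates 1 to 4 and at 4.82, 19.3, 22.1 and 4.18 CPM in WT replicates 1 to 4, a log2 fold change of 2.64 (SE 1.07). The monocyte list had an adjusted p of 0.320 without WT replicate 4 and 0.219 with quality weights, and the erythroid list lost its call without any 1 of WT replicates 1, 2, 3 and 4 or KO replicates 1 and 4, at adjusted p from 0.0509 to 0.746, and also with upper-quartile factors (0.0768), the filter of 1 CPM (0.109) or sex as a covariate (0.102). Without both WT replicate 4 and KO replicate 1 the neutrophil list still passed, with a median of 2.35 and an adjusted p of 1.81e-09 (adjusted p = 0.405 with an estimated correlation), while 10 of 20 monocyte markers were higher, at 0.759. Mean log2 CPM of the neutrophil list was -1.37, -1.18 and 1.06 in WT replicates 1 to 3. KO replicates 2 to 4 had 1.24 to 2.36, with the lowest value in KO replicate 4. The gap thus lay mainly against WT replicates 1 and 2, and WT replicate 3 was close to KO replicate 4. WT replicate 4, left out of that fit, was at 2.22, above KO replicates 2 and 4.

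A floxed allele can carry flanking sequence of another strain, and genes near Dot1l were compared with all others. None of the 191 tested genes within 10 Mb of Dot1l was called by edgeR or DESeq2. As edgeR called 0 genes anywhere and DESeq2 only 13, the lack of calls here tells little. At an unadjusted p under 0.05 were 6.81% of them and 6.59% of the genes elsewhere (Fisher's exact test, two-sided, p = 0.883).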

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

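The tests of CD8 transcripts in WT replicate 4 and of myeloid and eosinophil markers in KO replicate 1 were chosen after the values were seen. In 144 groups of 4 values taken by rule (totals, genes detected, list means and genes in WT and in KO), 21 had a library far from the other 3: WT replicate 4 in 11, KO replicate 1 in 9 and KO replicate 4 in 1. A rate of 1 in 20 would give 7.20. The rule took single genes by small p in these same data, and groups vary together, so 7.20 is only a rough guide. In 46 groups of genes named after their values were seen, 16 did, WT replicate 4 in 6 and KO replicate 1 in 10, and the chance figure does not apply to these.

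WT replicate 4 stood below the other WT libraries in the mean log2 CPM of the effector list (3.30), inhibitory receptors (2.29), NK receptors (1.38), S phase genes (3.82), mitosis genes (2.28), Polycomb-silenced genes (-1.26), helper lineage genes (2.84) and NK cell markers (1.03), and it was low in Klrk1 (57.9 CPM) and Klrc1 (4.49 CPM), and high in Cd27 (300.1 CPM), Dapl1 (158.9 CPM), Men1 (88.1 CPM), Tcf7 (2079 CPM), Ccr7 (519.0 CPM), Lef1 (655.6 CPM) and Cd14 (2.79 CPM). Lower depth is argued against: with every library thinned to the smallest total, its highest correlation with another library was 0.888. A sort mainly of cells other than CD8 T cells is argued against too, since Cd3e, Cd8a and Cd8b1 had a median ratio of 1.06 to the other 7 libraries. This ratio cannot exclude a smaller admixture. In the median member, markers of B cells, neutrophils, CD4 T cells and stroma lay 0.85, 1.34, 0.42 and 0.52 log2 units above the other 6 libraries. Those of monocytes, NK cells, erythroid cells and gamma delta T cells lay 1.80, 1.68, 0.44 and 0.33 log2 units below. Resting CD8 T cells in place of effector cells, by the sort or by a wrong label, remain open as a candidate explanation. The labels give a sort on presence of CD44, while Cd44 transcripts were at 22.0 CPM here and at 251.0 to 329.1 CPM in the other 6 libraries. Low Mki67 and Gzmb and high Tcf7, Ccr7 and Lef1 go the way of resting cells, and transcripts do not measure the surface protein. The effective number of Trbv segments was 15.9, against at most 14.3 in the other WT libraries, a narrow margin with no replicate of its own. No biological explanation was tested; by the labels this mouse carried Cre, as did WT replicates 2 and 3 and not WT replicate 1.

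KO replicate 1 stood above the other KO libraries in the mean log2 CPM of NK receptors (4.47), immediate early genes (4.69), monocyte, macrophage and dendritic cell markers (5.53) and gamma delta T cell markers (3.51). In single genes it was high in Tyrobp (82.8 CPM), Fcer1g (72.6 CPM), Gata2 (27.2 CPM), C1qc (40.2 CPM), Csf3r (83.6 CPM), Klra7 (13.6 CPM), Fos (24.6 CPM), Jun (55.4 CPM), Ccr7 (51.5 CPM), Il1b (43.8 CPM) and Lyz2 (718.7 CPM), and low in Cd8a (955.0 CPM), Klrk1 (155.1 CPM), Klrc1 (139.5 CPM) and Mki67 (1152 CPM). Although the labels give a sort for CD8 T cells, myeloid cells remain open as a candidate source, since 31 of 33 monocyte, macrophage, dendritic cell and neutrophil markers were higher than in the other KO libraries, with a median log2 ratio of 2.62. An admixture of cells as in WT replicate 4 also stays open: of the 100 genes most above the other 6 libraries there, 84 lay above all 6 here, though Lef1, 5.21-fold higher there, was 0.774-fold here, and the implied shares over the 100, with a median of 22.9% and an interquartile range of 29.1 percentage points, decide nothing where myeloid cells can add the same transcripts and the profile rests on 1 library. Eosinophils are undecided, with a median log2 ratio of 0.99 over 10 markers, and the eosinophil genes Epx and Prg2 were higher in KO replicate 4, at 10.01 and 18.4 CPM, than in KO replicate 1, at 2.99 and 7.83 CPM.

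Klf2 in KO replicate 4, at 236.7 CPM, lay above 170.1 to 176.8 CPM in the other 3 KO libraries.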

How the results depend on the processing

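Fits without both WT replicate 4 and KO replicate 1 were chosen after seeing the data; the cause of the changes given here was not tested. No edgeR or quality-weighted fit called a gene, and Dot1l kept its direction and stayed uncalled in every fit, with log2 fold changes from -0.07 to -0.01. DESeq2 called 13 genes with 8 libraries (4 higher, 9 lower, 6 at least 2-fold) and 94 without both libraries (18 higher, 76 lower, 32 at least 2-fold), where edgeR called 0. Genes at an unadjusted p under 0.05 numbered 790 in the first fit, 1279 with DESeq2, 1710 with quality weights, 1304 with no filter, 412 without WT replicate 1, 1317 without both libraries, 1308 without both and with sex, and 1435 without both in DESeq2. These counts come from unlike numbers of genes: 21568 in DESeq2 with 8 libraries, 21127 in DESeq2 without both, 22044 with no filter and 12310 in the others. Counts from different numbers of genes therefore cannot be compared directly. Of the 36 Polycomb-silenced genes 6 had enough counts to be tested, and whether greater depth would add others was not tested. With no gene called by edgeR, the planned share by expression level could not be formed under either grouping. Windows of 5 and 20 Mb around Dot1l also held 0 calls, which tells little where edgeR called 0 genes anywhere and DESeq2 13.

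Of 560 alternative values of lists, 78 reversed in direction, 68 of them with an adjusted p above 0.05 both times; of 1213 of named genes, 30 did, none of them called. Values of lists here are camera or fry adjusted p. With RLE factors, the direction reversed for CD4 0.997. With upper-quartile factors, the direction reversed for NK receptors 0.927 and CD4 0.929. With quality weights, the direction reversed for effector 0.173, inhibitory 0.907, NK receptors 7.21e-05, interferon 0.907, sterol 0.260, p53 0.578, Polycomb 0.907, helper 0.578, CD4 0.483, NK cells 0.219 and erythroid 0.578. With no low count filter, the direction reversed for sterol 0.733, heterochromatin 0.816 and CD4 0.733. With sex, the direction reversed for NK receptors 0.526. With fry, the direction reversed for homing 0.928 and cytokine receptors 0.928. Without WT replicate 4 and KO replicate 1, the direction reversed for effector 0.121, inhibitory 0.863, NK receptors 8.40e-07, interferon 0.930, sterol 0.930, Polycomb 0.717, helper 0.399, B cell 0.612, CD4 0.204 and NK cells 0.120. Without both and with sex, the direction reversed for effector 0.138, inhibitory 0.858, NK receptors 1.32e-08, interferon 0.902, sterol 0.946, Polycomb 0.507, Polycomb-silenced 0.946, helper 0.310, B cell 0.0825, CD4 0.248, NK cells 0.0924 and gamma delta 0.858. Without both and with an estimated correlation, the direction reversed for effector 0.569, inhibitory 0.962, NK receptors 0.208, interferon 0.962, sterol 0.962, Polycomb 0.962, helper 0.684, B cell 0.962, CD4 0.571 and NK cells 0.688. Among genes, log2 fold changes reversed with quality weights, Tnf -0.049, Gata2 -0.19, Ccr7 0.44, Gzmb -0.0056 and Cd44 -0.11, and without WT replicate 4 and KO replicate 1, Gata2 -0.65 and Cd44 -0.091, and without both and with sex, Gata2 -0.66, Ccr7 0.18 and Cd44 -0.083, and without both in DESeq2, Gata2 -0.67 and Cd44 -0.10. Calls were lost with the direction kept with upper-quartile factors, erythroid 0.0768, and with quality weights, respiratory chain 0.0550, DOT1L partners 0.0990 and monocyte 0.219, and with sex, erythroid 0.102, and with fry, effector 0.828, memory 0.739, receptor signalling 0.739, S phase 0.739, mitosis 0.739, glycolysis 0.739, respiratory chain 0.739, immediate early 0.449, DOT1L partners 0.739, monocyte 0.739, neutrophil 0.739 and erythroid 0.755, and without WT replicate 4 and KO replicate 1, monocyte 0.759 and erythroid 0.759, and without both and with sex, monocyte 0.902 and erythroid 0.730, and without both and with an estimated correlation, memory 0.250, receptor signalling 0.250, S phase 0.569, mitosis 0.569, glycolysis 0.714, respiratory chain 0.717, immediate early 0.208, DOT1L partners 0.609, monocyte 0.962, neutrophil 0.405 and erythroid 0.962, and with a filter of 1 CPM, erythroid 0.109, and with an estimated correlation, effector 0.936, memory 0.762, receptor signalling 0.762, S phase 0.762, mitosis 0.762, glycolysis 0.762, respiratory chain 0.762, immediate early 0.700, DOT1L partners 0.762, monocyte 0.762, neutrophil 0.762 and erythroid 0.895. Calls were gained with the direction kept with quality weights, homing 0.0452, and with no low count filter, NK cells 0.0193, and without WT replicate 4 and KO replicate 1, homing 0.00217, and without both and with sex, homing 0.00174. Lowest and highest values over the fits that leave out 1 library, for lists with a reversal or a moved call, were effector 0.000869 to 0.0831, memory 3.61e-05 to 0.0738, inhibitory 0.0737 to 0.995, NK receptors 4.99e-06 to 0.870, homing 0.00482 to 0.986, cytokine receptors 0.726 to 0.99997, interferon 0.0563 to 0.943, respiratory chain 1.26e-05 to 0.160, sterol 0.0999 to 0.932, p53 0.345 to 0.995, DOT1L partners 0.000874 to 0.116, Polycomb 0.427 to 0.917, Polycomb-silenced 0.0455 to 0.746, heterochromatin 0.726 to 0.993, helper 0.112 to 0.823, B cell 0.00516 to 0.972, CD4 0.323 to 0.99997, NK cells 0.0456 to 0.823, monocyte 1.24e-05 to 0.320, erythroid 0.000134 to 0.746 and gamma delta 0.0275 to 0.823, and for log2 fold changes of genes Gata2 -0.53 to 3.29, Klrc1 -0.50 to 0.12, Klrc2 -0.66 to 0.057, Tcf7 -2.52 to 0.65, Ccr7 -5.18 to 1.75, Gzmb -0.23 to 0.65, Cd44 -0.078 to 0.55 and Cd8a -0.064 to 0.21.

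The replicate numbers were not taken to pair the samples, since same-numbered libraries correlated at 0.02, 0.45, 0.20 and -0.07 in their deviations from the group means, and not every library correlated best with its own number. With the replicate number as a block edgeR called 0 genes, with 749 at an unadjusted p under 0.05, the effector list had an adjusted p of 0.0853, lists that gained a call towards higher values in KO were B cell 0.00116 and gamma delta 0.0472, lists reversed were NK receptors 0.609, cytokine receptors 0.987 and CD4 0.835, and genes reversed were Klrc1 0.38, Klrc2 0.27 and Cd8a -0.033.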

Other observations

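Leaving out WT replicate 4 and KO replicate 1, and the count of male libraries set against the lower NK receptor list, were chosen after the results were seen. Homing genes were mostly lower in KO, in 17 of 24 members, without passing camera in the first fit of all 8 libraries (adjusted p 0.812, and 0.936 with an estimated correlation). S1pr1, which guides lymphocytes out of tissues, was at 451.9 ± 146 CPM in WT and 285.1 ± 20.4 CPM in KO, and Selplg, which encodes the selectin ligand PSGL-1, at 1054 ± 162 and 766.1 ± 43.4 CPM (SD, n = 4 each); in both, all KO libraries lay below all WT libraries. S1pr4 had a log2 fold change of -0.43 (SE 0.16). The list passed towards lower values in KO with quality weights on all 8 libraries, at an adjusted p of 0.0452, and without WT replicate 4, at 0.00482. Without both WT replicate 4 and KO replicate 1 it was 0.00217, and 0.250 with an estimated correlation. The quality weight of WT replicate 4 was only 0.091, so the weighted fit comes near to leaving it out. Mean log2 CPM of the list was 7.19, 6.78 and 6.71 in WT replicates 1 to 3 and 6.61, 6.52 and 6.92 in KO replicates 2 to 4. KO replicate 4 thus lay above WT replicates 2 and 3, and the highest value was that of WT replicate 1, the library without Cre.

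Other lists did not pass in the first fit of all 8 libraries: cytokine receptors (adjusted p 0.957), interferon-stimulated genes (0.561), sterol biosynthesis (0.957), p53 targets (0.620), heterochromatin machinery (0.876), helper lineage genes (0.395), and markers of CD4 T cells (0.997), NK cells (0.395), B cells (0.291), gamma delta T cells (0.112) and stroma (0.385). B cell markers passed towards higher values in KO without WT replicate 1, KO replicate 2 or KO replicate 3 (adjusted p 0.00516, 0.00833 and 0.0351), gamma delta T cell markers without KO replicate 2 or 3 (0.0294 and 0.0275), and NK cell markers without KO replicate 2 (0.0456) or, with all 8 libraries, with no low count filter (0.0193). With the replicate number as a block B cell and gamma delta T cell markers passed as well (0.00116 and 0.0472). Without KO replicate 1 B cell markers reversed to lower values (0.776), and gamma delta T cell and NK cell markers had 0.823 each. With an estimated correlation and all 8 libraries the adjusted p was 0.936 for B cell, 0.762 for gamma delta T cell and 0.936 for NK cell markers. Tox2, of the inhibitory list, had a log2 fold change of 1.16 (SE 0.60), and Cd244a, of the NK receptor list, 1.74 (SE 0.77), or 0.95 without KO replicate 1.

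T cell receptor use differed between libraries. In KO replicate 4, Trbv14 made up 74.4% of the 8134 Trbv counts, an effective number of 3.08 segments, while the effective number was 10.1 to 15.9 in the other 7 libraries. KO replicate 3, male by Ddx3y at 105.3 CPM and Kdm5d at 59.9 CPM, had Eif2s3y at 5.12 CPM against 85.9 to 91.6 CPM in the other 3 male libraries.

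In the 6 libraries without WT replicate 4 and KO replicate 1, the lower NK receptor list was weighed against 3 technical explanations, of which a difference in sex is argued against, since each group of 3 held 1 male library, a difference of 0. A strain variant stays open: the 20 tested genes from Tulp3 to Ybx3 on chromosome 6 that are not Klr genes had a median log2 fold change of 0.10, against -0.99 for the 20 Klr genes, but they went both ways, 6 lower, and need not fall with the receptors. All 16 lower Klr genes lie in the stretch from Klre1 to Klra1, where only Klra14-ps was not lower (0.12). Outside it, Klrb1c, Klrb1f and Klra2 were not lower (0.032, 0.96 and 0.86). That stretch holds none of the genes that are not Klr genes, so their median cannot speak for it. Fewer NK cells stay open, although the labels give a sort for CD8 T cells by surface markers. Tyrobp, Fcer1g and Itga2 were higher, with a median of 0.35 (SE 0.23 to 0.34) and Ncr1 too low to be tested. But myeloid cells also express Tyrobp and Fcer1g, and neutrophil markers were higher in KO (median 2.35), mainly against WT replicates 1 and 2. Of 10 NK cell markers 6 were lower, with a median of -0.35. These markers include Klra8 (-0.38), one of the 20 Klr genes, and Tyrobp and Fcer1g, which are also in the NK receptor list. They are thus not a separate measure of NK cells. The 10 splits of these libraries are too few for a share under 0.05; 1 of 10, the real one, gave a camera p as small as its 1.20e-07, and the lowest of the others gave 6.10e-05. Loss of Dot1L stays open beside these, only as a hypothesis for other mice.

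For all 8 libraries, the real split was set beside the other splits into 4 and 4. The real split called 0 genes and the highest other count was 3, from the split that parts male from female libraries; as each of the 35 splits is bound to reach 0, this count tells nothing of chance. For the mitosis list 26 of 35 splits gave a camera p as small as the real 1.61e-06 (smallest other 4.23e-10), for the effector list 35 (real 0.00826, smallest other 1.69e-09), for the naive and memory list 9 (real 8.07e-05, smallest other 8.31e-07), for the neutrophil list 6 (real 1.25e-08, smallest other 1.73e-14), for the T cell receptor signalling list 3 (real 6.40e-07, smallest other 1.40e-07) and for the immediate early list 2 (real 1.48e-06, smallest other 6.44e-09). Chance is not excluded for any of these 6 lists.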
